A study of Mus musculus with 12 samples.

How the data were processed

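The 12 arrays hold total RNA of Ebf1-/- pre-pro-B cells of C57BL/6 mice. Per the labels' protocols, the cells were kept on OP9 stroma, a mouse bone marrow stromal line, with 4% serum, stem cell factor and Flt3 ligand at 10 ng/ml and interleukin-7 at 5 ng/ml. Per the same protocols they were spin-infected with the control, EBF1 or PAX5 retrovirus, GFP-positive cells were sorted after 2 days, and RNA was purified with TRIzol and RNeasy columns. Biotin-labelled cRNA was made by the standard Affymetrix protocol, per the labels.

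The deposited values are intensities per probe set on a linear scale, with 1 column per array. How the authors summarised probes and normalized arrays is not given in the sources used here. From the values, the arrays share a scale within a set, with medians of 55.1 to 60.6 in set 1 and 65.3 to 68.9 in set 2, and 2.5% to 3.05% of probe sets on each array are listed at exactly 1. That looks like a floor for most dim probe sets, but the lowest value of each array lies below it, at 0.57 to 0.98. Values near 1 have no order, and a log2 change of a dim gene understates its true change because of the added constant. No per-sample column was left out. Gene names came from the platform annotation: of 45037 probe sets 34945 carried 1 gene symbol, 932 several and 9160 none, and 34741 of the first kind matched the GRCm38.p6 gene table by Entrez ID, with 0 symbols replaced and 204 kept as annotated. No coordinates are given, since no genome build is stated for the values.

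Intensities were used as log2(intensity + 16) without further normalization. Each gene was represented by its brightest probe set over all arrays among those with 1 symbol, which gave 18193 genes, with no filter on level. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, with the data.table package, version 1.17.8, to read tables), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Each transduced group was compared with the controls of its own set, the difference of the EBF1 and PAX5 changes was tested in the same fit, and the control sets were compared in a fit of 4 group means over all 12 arrays. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

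The gene lists, the rule for naming genes, most alternatives and a design that counted all 12 arrays separately were written before the data were examined. That design was then replaced by a fit that counts each hybridisation once, because control arrays of equal number in the 2 sets looked like the same hybridisation summarised 2 times. Over 12889 bright probe sets (mean log2 above 8), such pairs had a robust SD of 0.039 to 0.094, against 0.287 to 0.374 for unequal numbers, and their deviations from the group means correlated at 0.86, 0.88 and 0.85. In that fit the gene-wise offset between the control sets was removed, control arrays of equal number were averaged, and PAX5 arrays 2 and 3 (robust SD 0.077, against 0.211 to 0.359 for other pairs within a group) were averaged, which left 3 control, 3 EBF1 and 2 PAX5 samples, 5 residual degrees of freedom and 3.53 prior degrees of freedom. Several ways of counting the arrays were tried before this one was chosen and their call counts had been seen. The fit as first written called 201 genes with EBF1, 357 with PAX5, 156 for the difference and 23 shared by both. A further trial that compared each transduced group with the other set's controls called many more genes and is not reported, since it compares values summarised separately.

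Control and EBF1 arrays share replicate numbers in the labels, and deviations of equal numbers correlated at 0.21, 0.40 and 0.22, all above 0.1, so the numbers were taken to pair these arrays. The main fit nevertheless treated them as unpaired, and the pairing entered only the alternatives with a replicate block. For control and PAX5 arrays of set 2 the correlations did not all pass that limit, and the arrays were taken to share only a number.

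The 19 gene lists came from general knowledge of blood cell development: early B-lineage factors, pre-B-cell and B-cell receptor, V(D)J recombination, T-lineage, natural killer and innate lymphoid, myeloid, dendritic, stem and progenitor, erythroid and megakaryocyte, mast cell and basophil, OP9 stroma, cell cycle, interleukin-7 signalling, MHC class II, chromatin architecture, interferon response, p53 targets, immediate-early and unfolded protein response. They hold 384 genes, of which 351 were measured. Lists were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 19 lists of a comparison, and again with an estimated correlation, under which 0 lists passed in any of the 3 comparisons. Limma's fry, which asks whether a list's genes move on balance in 1 direction, passed 1, 3 and 3 lists for EBF1, PAX5 and the difference.

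The naming rule takes, for EBF1 and PAX5 each, the 8 largest rises and up to 8 largest falls among genes past the threshold whose 3 transduced arrays all lie on the same side of their 3 controls and whose higher group mean exceeds the median of all probe sets. It adds up to 3 members of each list past the threshold, 5 genes in each direction for the difference test, 2 in each direction for the control sets, and Ebf1 and Pax5 throughout.

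The fit was tested on simulated data with 18193 genes, with 100 genes changed by 1 and 100 by 3 in log2 in each comparison. For EBF1 it recovered 80% of changes of 1 in log2 and 100% of changes of 3, with 14 unchanged genes among 194 calls, and for PAX5 78% and 100%, with 12 unchanged genes among 190 calls. Changed genes were drawn from those above the median level, every array carried the full change, and noise was independent between samples. The rates therefore do not carry over to dim genes, paired arrays or an array with a weaker response. Alternatives covered normalization between arrays, a filter on dim genes, the arrays in the fit, the variance model, array weights, replicate blocks, the gene summary, thresholds, pseudocounts of 1 and 64, list tests and leaving out each array in turn.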

Results

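Gene expression was measured on 12 one-colour Affymetrix arrays of mouse pre-pro-B cells, the progenitors in which B lymphopoiesis stalls when the transcription factor EBF1 is missing. Ebf1-/- progenitors of strain C57BL/6 were transduced with a retrovirus carrying GFP alone (the MigR1 control), EBF1 with GFP, or PAX5 with GFP, and GFP-positive cells were sorted 2 days later. The labels give 4 groups of 3 arrays in 2 sets: control and EBF1 arrays in set 1, control and PAX5 arrays in set 2. The series belongs to a study of how chromatin organisation changes between the pre-pro-B and pro-B stages, and the arrays ask which transcripts each factor changes in cells that lack EBF1. Median intensity over 45037 probe sets ran from 55.1 to 60.6 in set 1 and from 65.3 to 68.9 in set 2, and the number of arrays limits the precision. Control arrays of equal number in the 2 sets differed by less than replicate arrays do (robust SD of the log2 difference 0.039 to 0.094, against 0.287 to 0.374 for unequal numbers), so the 3 control pairs were counted as 3 samples. PAX5 arrays 2 and 3 also differed less (0.077) than any other pair within a group (0.211 to 0.359) and were counted as 1 sample, which leaves 2 PAX5 samples. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical.

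Ebf1 transcript was bright in every group, but where its probes lie relative to the mutated part and to the viral insert is not given, so the level checks nothing about the labels. Its brightest probe set read 2116 ± 78.1 (SD, n = 3) in control set 1, 2093 ± 332 (n = 3) in EBF1 cells, 1987 ± 84.0 (n = 3) in control set 2 and 1994 ± 109 (n = 2) in PAX5 cells, and none of its 5 probe sets passed the test in either comparison. Pax5, the transcription factor of B cell commitment, rose in PAX5 cells from 9.93 ± 2.56 (n = 3) to 1380 ± 663 (n = 2), with a log2 change of 5.67 (SE 0.27, limma adjusted p = 4.4e-05). Log2 changes are of intensity plus 16, so for genes this dim in the controls their size depends on that constant. The change of Pax5 ran from 2.76 to 6.92 over the alternatives, which include the mean of its 2 probe sets as well as other constants. EBF1 cells held Pax5 at 83.8 ± 15.9 (n = 3) beside 65.9 ± 12 (n = 3) in their controls, a log2 change of 0.28 with adjusted p = 0.72 by limma. The second Pax5 probe set did not pass in PAX5 cells, with a log2 change of -0.14 (adjusted p = 0.91).

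EBF1 raised parts of the pre-B-cell receptor. Ms4a1, which encodes a B cell surface protein, rose from 18.7 ± 4.01 to 5184 ± 2018 (SD, n = 3 each), with a log2 change of 7.15 (SE 0.29, limma adjusted p = 5e-05) that ran from 5.91 to 7.97 over the alternatives. Vpreb1 and Igll1, the surrogate light chain, rose from 32.0 ± 12.4 to 4479 ± 1975 and from 159 ± 4.50 to 6212 ± 2468, by 6.48 and 5.08 in log2, with adjusted p = 7.9e-05 for both, while the other Igll1 probe set stood at 0.23 and did not pass. Cd79b, a signalling chain of the receptor, rose from 9.32 ± 2.52 to 1424 ± 854 (log2 change 5.61, adjusted p = 0.0016). Genes better known from other cell types also rose: Gzma, a protease of cytotoxic lymphocytes, by 6.43 in log2 (adjusted p = 0.00012), Tnnt2, cardiac troponin T, by 6.79 (0.00012), Apoa4, an apolipoprotein, by 6.01 (0.0015), and Tubb3, a tubulin best known from neurons, by 5.20 (0.0031). These sizes depend on the pseudocount. Tnnt2 lay between 4.57 and 9.01 over the alternatives, which also include the mean of its 3 probe sets, of which 2 passed and the lowest stood at 0.1. In all, 40 of 18193 genes passed limma's unpaired test at Benjamini-Hochberg adjusted p under 0.05, 35 higher and 5 lower with EBF1. At unadjusted p under 0.05, 2114 passed where 910 are expected by chance. Both genes lower with EBF1 that met the naming rule fell modestly: Htra1, a secreted serine protease, from 206 ± 45.2 to 50.5 ± 21.5 (log2 change -1.77, adjusted p = 0.035), and Lmo4, a LIM-domain regulator of transcription, from 827 ± 142 to 352 ± 56.3 (-1.19, 0.034). The other genes that fell, named after their values were seen, were Rex2 (-1.56), Hmcn1 (-0.88) and 1700021F07Rik (-0.82). With control and EBF1 arrays of equal number paired, 69 genes passed, 66 higher and 3 lower, but Htra1 and Lmo4 did not (adjusted p = 0.06 for both, within 0.0032 to 0.21 and 0.0065 to 0.17 over all alternatives by limma). With all 12 arrays counted separately, as first planned, 201 passed. Leaving out control array 1, 2 or 3 left 10, 13 and 13 genes, EBF1 array 2 left 19, PAX5 array 1, through the shared variance estimate, 11, and EBF1 array 3 left 406.

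Among the 19 gene lists, the pre-B-cell and B-cell receptor list moved most clearly with EBF1. Of its 23 measured genes 6 rose and 0 fell over all genes tested, and 10 rose and 2 fell adjusted over the list alone. Limma's camera gave adjusted p = 4.5e-10 for the list, and adjusted p = 0.23 with an estimated correlation. Beside Ms4a1, Vpreb1, Igll1 and Cd79b, the members that rose were Cd79a, the partner chain of Cd79b, by 3.56 in log2 (SE 0.34, adjusted p = 0.0061), and Cd24a, the heat-stable antigen, by 2.80 (SE 0.20, 0.00087), both chosen after their values were seen. Of 22 early B-lineage transcription factors 2 rose and 0 fell, 3 and 0 adjusted over the list alone: Spib by 3.27 (SE 0.41, adjusted p = 0.027) and Foxo1 by 2.94 (SE 0.38, 0.031). Of 4 Foxo1 probe sets 1 passed (log2 changes 0.07 to 2.94), and the call was lost in the mean of the 4. Not passing were Pou2af1 at 2.48 (0.087) in that list, Blnk at 3.33 (0.087) in the receptor list, and Rag1, which cuts antigen receptor genes, at 2.73 (0.13).

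Single members of other lineage lists rose with EBF1. Hes1, a repressor acting downstream of Notch, was 1 of 21 T-lineage genes (log2 change 3.28, adjusted p = 0.023), and 1 rose and 0 fell adjusted over the list alone. Gzma was 1 of 21 natural killer and innate lymphoid genes, of which 1 rose and 7 fell adjusted over the list alone. Those 7 included Zbtb16 and Id2, regulators of innate lymphoid cells, at -1.30 (adjusted p = 0.10 over all genes) and -1.04 (0.15). Ly6d, a surface protein of B-directed lymphoid progenitors, was 1 of 15 dendritic list genes (4.17, adjusted p = 0.021), with 1 rising and 3 falling adjusted over the list alone. The calls of Foxo1, Spib, Hes1, Ly6d, Htra1 and Lmo4 were lost when any 1 of the 3 control arrays was left out, with adjusted p of up to 0.21 over the alternatives.

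The other 14 lists had 0 of 254 members past limma's test over all genes with EBF1, and 49 at unadjusted p under 0.05. Camera nevertheless placed the stem and progenitor list lower (22 genes, median log2 change -0.35, adjusted p = 0.00045; adjusted p = 0.42 with an estimated correlation). Adjusted over the list alone, 0 of its genes rose and 4 fell. These included Mycn at -1.84 (adjusted p = 0.087 over all genes) and Flt3, the receptor of a progenitor cytokine, at -0.87 (0.19). Immediate-early genes, which respond to handling, were placed higher (16 genes, median 0.35, adjusted p = 0.012, and adjusted p = 0.42 with an estimated correlation), with 2 rising and 0 falling adjusted over the list alone. Of the 14, the stromal list also passed camera and the other 11 did not. Adjusted over the list alone, the counts that rose and fell were 1 and 0 of 11 V(D)J recombination genes, 1 and 3 of 26 myeloid genes, 1 and 0 of 12 erythroid and megakaryocyte genes, 3 and 1 of 20 interleukin-7 signalling genes, and 0 and 1 of 12 MHC class II genes. No gene passed in either way, within the list alone or over all genes by limma, among 13 mast cell and basophil genes (2 at unadjusted p under 0.05), 25 cell cycle genes (2), 28 chromatin architecture genes (1), 17 interferon-stimulated genes (1), 17 p53 targets (4) or 16 unfolded protein response genes (2). Median, mean and camera direction differed in sign for the myeloid, erythroid, interleukin-7 and p53 lists.

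Transcripts of mesenchymal stroma, the type of cell in the OP9 feeder layer, were uneven across the EBF1 arrays. Camera placed the 19 stromal genes higher with EBF1 (median 0.84, adjusted p = 0.00053; adjusted p = 0.42 with an estimated correlation), while 0 passed limma's test over all genes, 0 adjusted over the list alone and 1 at unadjusted p under 0.05. Against the control mean, their median log2 difference was 0.44, -0.10 and 2.14 in EBF1 arrays 1, 2 and 3, and 0.50, -0.31 and -0.16 in the control arrays of set 1. In EBF1 array 3 the chemokine gene Cxcl12 read 3366, the proteoglycan gene Bgn 2727, the collagen gene Col1a2 2018 and the fibronectin gene Fn1 1962. Control array 1 of set 1 read 128, 550, 376 and 344 for these genes, and control array 3 read 129, 73, 99 and 63. Across the genes that rose with EBF1, the median log2 difference from the control mean was 4.49, 3.40 and 2.41 in EBF1 arrays 1, 2 and 3, and array 3 held the lowest level of Ms4a1, Vpreb1 and Cd79b among them.

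**Figure D1:**
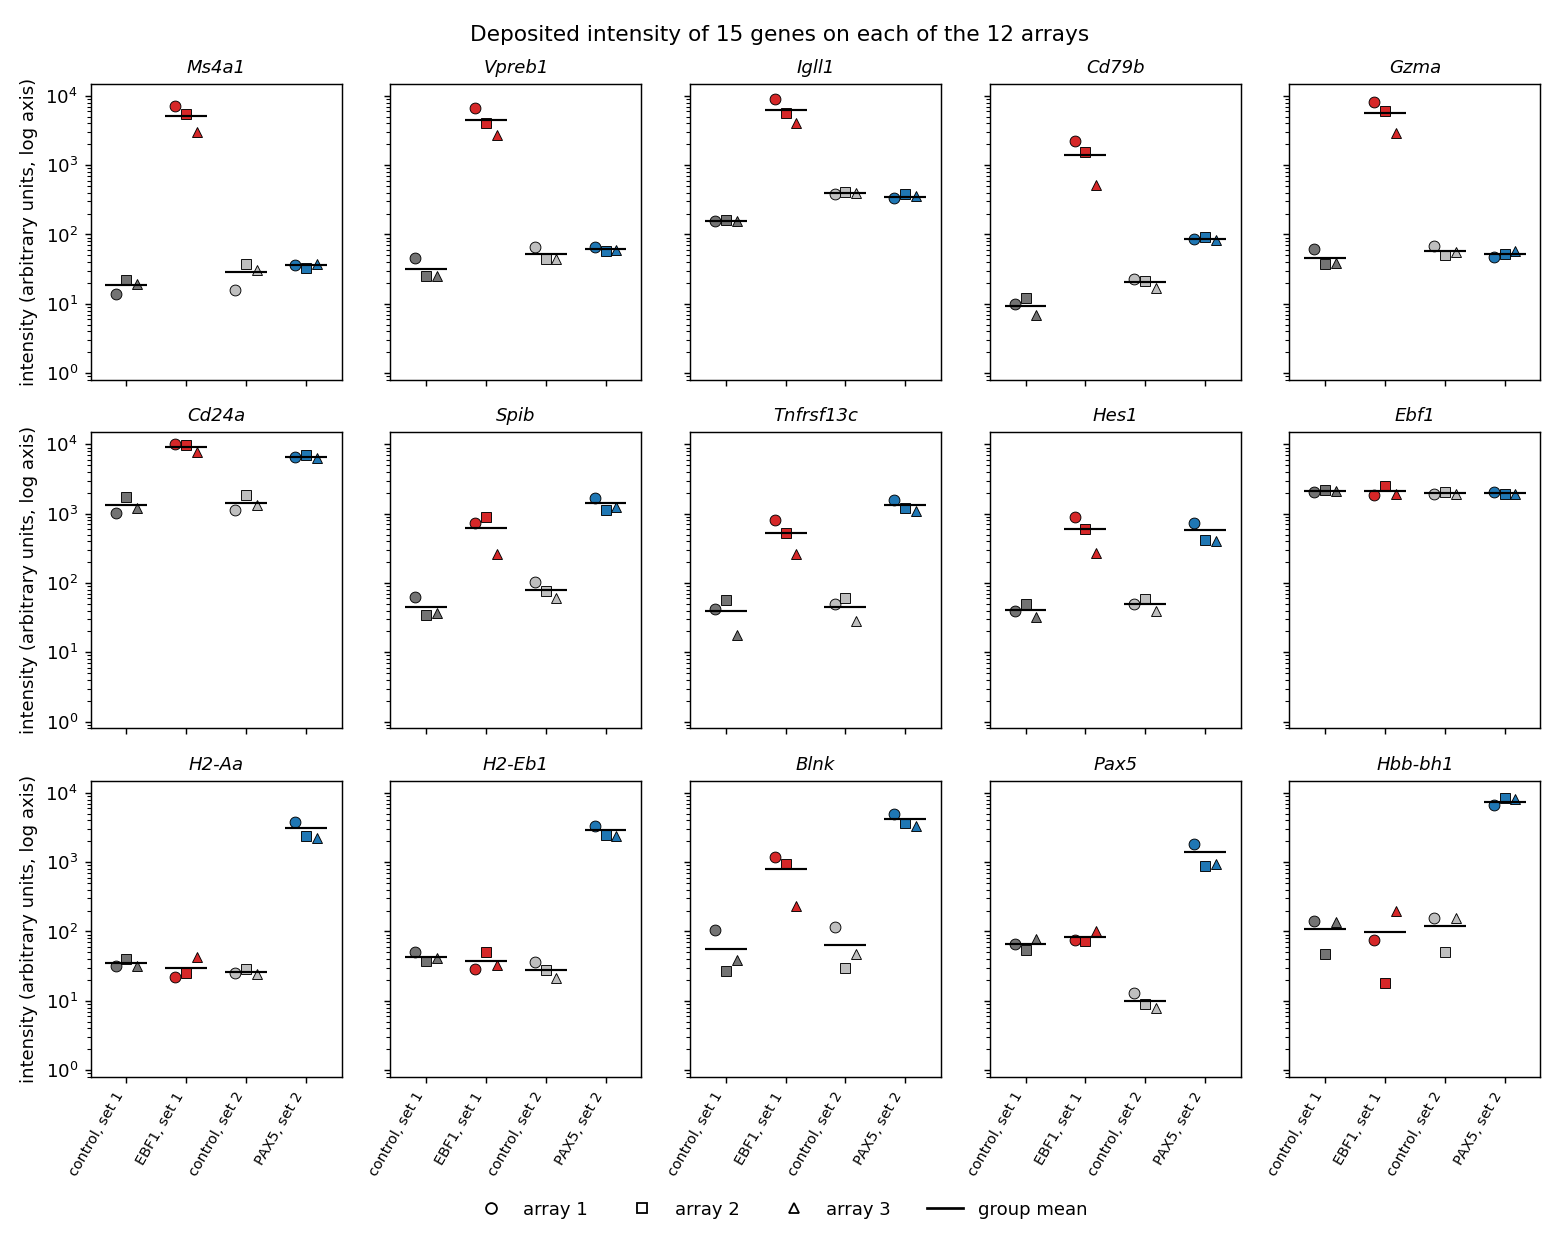
Deposited intensity (arbitrary units, log axis) of 15 genes on each of the 12 arrays, with marker shape giving the array number and the bar the group mean, in which PAX5 arrays 2 and 3 count as 1 sample. Ms4a1 averages 5184 in EBF1 cells against 18.7 in their controls, H2-Aa averages 3075 in PAX5 cells against 26.2, and Ebf1 averages between 1987 and 2116 in all 4 groups.

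**Figure D2:**
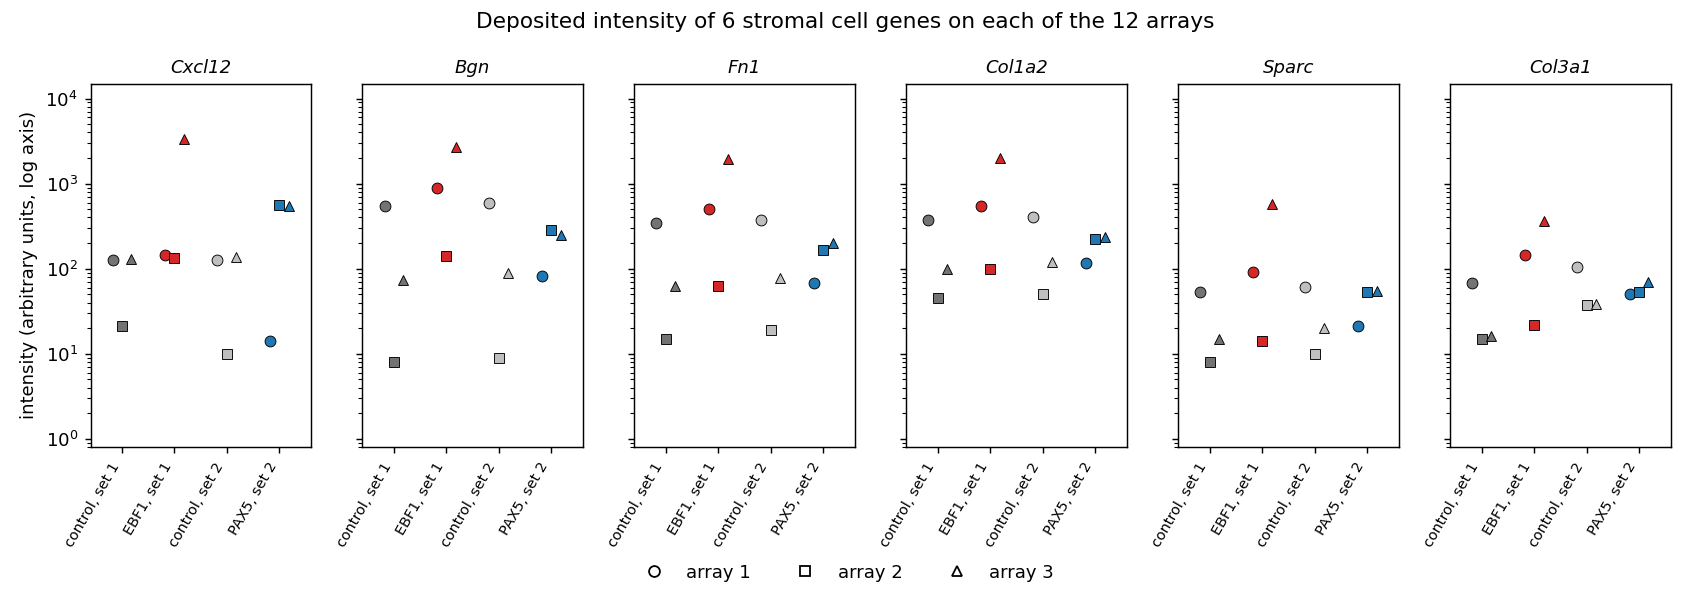
Deposited intensity (arbitrary units, log axis) of 6 genes of the stromal list on each of the 12 arrays, with marker shape giving the array number. EBF1 array 3 lies highest in every panel, with Cxcl12 at 3366 and Bgn at 2727.

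PAX5 raised 5 of 12 MHC class II genes. H2-Aa, H2-Eb1 and H2-Ab1, which encode chains of the class II molecule that presents peptides, rose by 6.15, 6.03 and 5.50 in log2: H2-Aa from 26.2 ± 2.21 (SD, n = 3) to 3075 ± 1090 (n = 2), H2-Eb1 from 28.2 ± 7.56 to 2872 ± 593, and H2-Ab1 from 35.4 ± 8.27 to 2331 ± 597, with limma adjusted p = 1.8e-05, 1.1e-05 and 1.1e-05. Blnk, the adaptor that couples the B cell receptor to downstream signalling, rose from 64.2 ± 45.5 to 4186 ± 977 (log2 change 5.84, SE 0.66, adjusted p = 0.0052). Tnfrsf13c, the receptor for the B cell survival factor BAFF, rose by 4.49 (SE 0.44, 0.0028). Hbb-bh1, an embryonic beta-like globin, rose from 121 ± 61.8 to 7462 ± 1103 (5.89, SE 0.69, 0.0063), and Cartpt, a neuropeptide precursor, by 4.20 (SE 0.29, 0.00047). In all, 159 of 18193 genes passed at adjusted p under 0.05, 145 higher and 14 lower, with 1720 at unadjusted p under 0.05 where 910 are expected.

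The largest falls with PAX5 were smaller than the largest rises. Morc1, known from germ cells, fell from 645 ± 242 to 51.5 ± 0.113 (log2 change -3.22, SE 0.52, adjusted p = 0.031 by limma), and Gbp8, a guanylate-binding protein, from 448 ± 191 to 39.0 ± 0.513 (-2.98, 0.015). The small SDs with PAX5 come from averaging arrays 2 and 3 first: PAX5 arrays 1, 2 and 3 read 51, 59 and 44 for Morc1 and 39, 41 and 38 for Gbp8. Fcer1g, the signalling chain shared by Fc and natural killer receptors, fell from 4571 ± 359 to 1837 ± 380 (-1.32, 0.016), and Hnrnpll, a splicing regulator of lymphocytes, from 1515 ± 156 to 659 ± 139 (-1.19, 0.012). Lhfpl2 (-2.07, adjusted p = 0.008), Rhobtb1 (-2.01, 0.026), Rtn4rl1 (-1.32, 0.021) and Kifc5b, a kinesin (-1.26, 0.011), also fell. With all 12 arrays counted separately, as first planned, 357 genes passed with PAX5. Leaving out control array 1, 2 or 3 left 100, 97 and 81 genes, and leaving out PAX5 array 1, after which the lone remaining sample is assumed to vary like the other groups, left 28: all 8 of the falls named here, and the calls of Hbb-bh1, Blnk, Tnfrsf13c, Spib, Irf4, Cd24a, Hes1, Ccr2, Polm, Itgax and Vwf, were lost without it.

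Of the 12 measured MHC class II genes 5 rose and 0 fell with PAX5, and 9 rose and 0 fell adjusted over the list alone, with a median log2 change of 1.67. Camera gave adjusted p = 9.6e-19, and adjusted p = 0.12 with an estimated correlation. The members not yet described were Cd74, the invariant chain, at 3.84 (SE 0.30, adjusted p = 0.00094) and Ciita, the transactivator of class II genes, at 2.40 (SE 0.14, 0.00014), both named after their values were seen. Of 23 receptor list genes 3 rose and 0 fell, 7 and 0 adjusted over the list alone (camera adjusted p = 3.2e-10, and adjusted p = 0.12 with an estimated correlation): Blnk, Siglecg, an inhibitory lectin of B cells, at 3.74 (SE 0.22, 0.00015), and Cd24a at 2.22 (SE 0.22, 0.0028). Ms4a1 stood at 0.26 (adjusted p = 0.90), Vpreb1 at 0.20 (0.93) and Igll1 at -0.17 (0.93). Of 22 early B-lineage factors 3 rose and 0 fell, 9 and 0 adjusted over the list alone (camera adjusted p = 4.9e-09, and adjusted p = 0.18 with an estimated correlation): the transduced Pax5, Spib at 3.93 (SE 0.46, 0.0063) and Irf4 at 2.72 (SE 0.34, 0.0085). These counts and list tests include Pax5, the gene the virus carried, and no value without it is given. The list's median log2 change was 0.21 and its mean 1.01. Bcl11a at 1.74 (0.056) and Irf8 at 1.89 (0.064) did not pass.

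Other lineage lists held 1 or 2 changed genes each with PAX5. In the T-lineage list 2 of 21 rose, Hes1 by 3.14 (SE 0.44, adjusted p = 0.016) and Dtx1, a Notch pathway ubiquitin ligase, by 1.90 (SE 0.16, 0.0015). The other Dtx1 probe set stood at -0.02, and the Dtx1 call was lost in the mean of both. Adjusted over the list alone, 3 T-lineage genes rose and 5 fell, among them Lat and Zap70, which relay T cell receptor signals, at -1.37 (adjusted p = 0.27 over all genes) and -0.93 (0.28). Ccr2, a chemokine receptor of monocytes, rose from 310 ± 64.6 to 2780 ± 886 (3.08, SE 0.31, 0.0031) as 1 of 26 myeloid genes, while Lyz2 stood at -0.15 (0.84). Itgax, an integrin of dendritic cells, rose by 1.56 (SE 0.22, 0.016) as 1 of 15 dendritic genes, and Siglech stood at 0.13 (0.97). Polm, a polymerase used in DNA end joining, rose by 1.96 (SE 0.26, 0.012) as 1 of 11 recombination genes, and Vwf by 1.63 (SE 0.29, 0.044) as 1 of 12 erythroid and megakaryocyte genes. The Vwf call was lost under 11 of 20 alternatives, among them leaving out any 1 control or EBF1 array and either pseudocount, with adjusted p from 0.016 to 0.17. Fcer1g was the 1 that fell of 21 natural killer genes. Adjusted over the list alone, the counts that rose and fell were 1 and 0 for myeloid, 1 and 1 for dendritic, 1 and 0 for recombination, 1 and 1 for erythroid and 1 and 4 for natural killer genes. None of these lists passed camera.

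The other 10 lists had 0 of 193 members past limma's test over all genes with PAX5, and 25 at unadjusted p under 0.05. Camera placed immediate-early genes higher (16 genes, median 0.34, adjusted p = 0.00015, and adjusted p = 0.58 with an estimated correlation), with 3 rising and 0 falling adjusted over the list alone. Fos (log2 change 3.18, adjusted p = 0.072), Jun (2.69, 0.12) and Dusp1 (1.96, 0.054) were brightest in PAX5 array 1, at 1764, 1274 and 1243, against 493, 184 and 569 in array 2. Camera placed cell cycle genes lower (25 genes, median -0.14, adjusted p = 0.012, and adjusted p = 0.81 with an estimated correlation) and unfolded protein response genes lower (16 genes, median -0.16, adjusted p = 0.012, and adjusted p = 0.58 with an estimated correlation), with 0 members of either past limma's test within the list alone and 2 each at unadjusted p under 0.05. The cell cycle shift lay in PAX5 array 1: the list's median log2 difference from the control mean was -0.26, 0.03 and -0.03 in PAX5 arrays 1, 2 and 3. Adjusted over the list alone 2 of 22 stem and progenitor genes rose and 1 fell, with 5 at unadjusted p under 0.05. The same limma count was 0 for the mast cell (0 at unadjusted p under 0.05), stromal (1), interleukin-7 (6), chromatin architecture (1), interferon (0) and p53 (3) lists, none of which passed camera. Median, mean and camera direction differed in sign for the T-lineage, natural killer, stem and stromal lists.

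The responses to EBF1 and PAX5 were tested against each other gene by gene. Ms4a1 and Vpreb1 rose more with EBF1, by 6.89 (SE 0.32) and 6.28 (SE 0.33) in log2, with adjusted p = 3.5e-05 and 5.9e-05 by limma. Tnnt2 (6.62, adjusted p = 0.00015), Gzma (6.54, 0.00011) and Apoa4 (6.08, 0.00096) did so too. With PAX5 the class II genes H2-Aa, H2-Eb1 and H2-Ab1 rose more, with EBF1 minus PAX5 differences of -6.32 (SE 0.25), -6.17 (SE 0.21) and -5.53 (SE 0.20) and adjusted p = 1.4e-05, 1e-05 and 1e-05. Hbb-bh1 (-6.28, 0.0036) and the transduced Pax5 (-5.38, 5.1e-05) had differences of the same sign. The responses differed for 353 genes, higher with EBF1 for 107 and with PAX5 for 246, with 3096 at unadjusted p under 0.05 where 910 are expected. Of the genes called in the separate tests, 30 of the 40 for EBF1 and 120 of the 159 for PAX5 were among them. With all 12 arrays counted separately, as first planned, 156 genes differed. In the fit that counts each hybridisation once, the controls cancel from the difference. Its p-values leave out error in the gene-wise offset between the control sets, which the fit of 12 arrays includes. Leaving out EBF1 array 1, 2 or 3 gave 167, 154 and 575 genes, and leaving out PAX5 array 1 gave 55 and ended the call of Hbb-bh1. The labels give no batch of hybridisation, so whether the EBF1 and PAX5 arrays were hybridised together is not known.

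**Figure D3:**
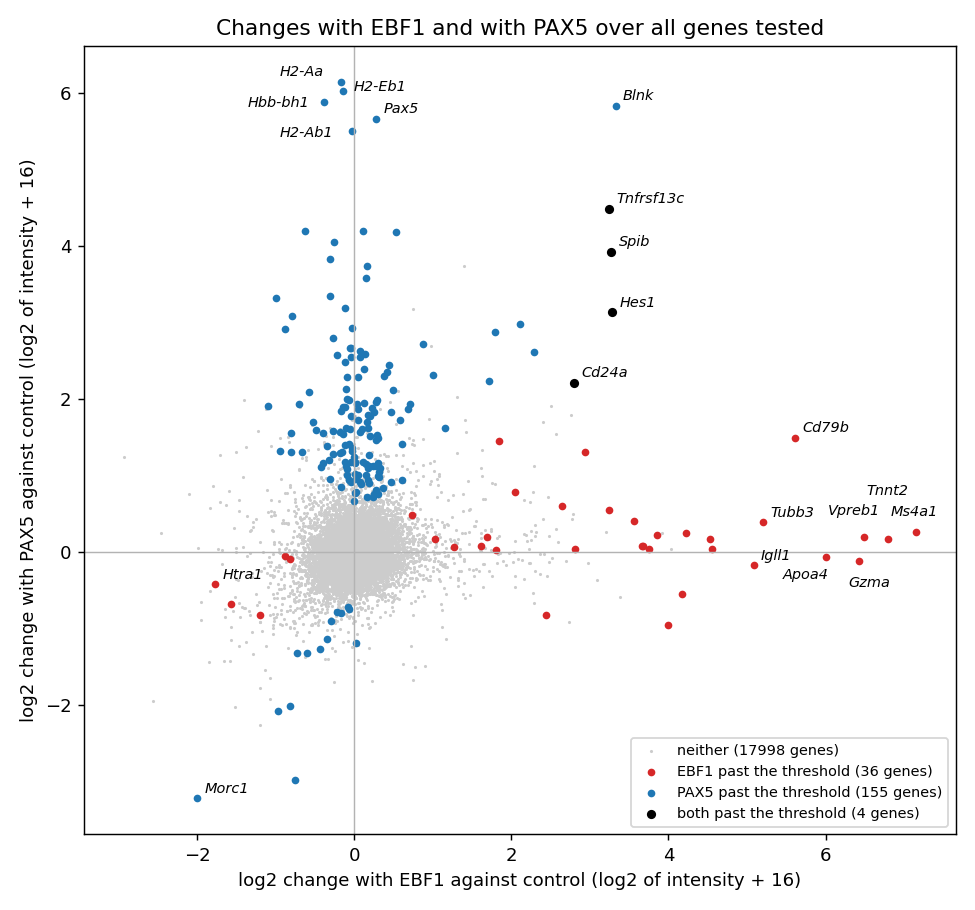
Log2 change with EBF1 (horizontal axis) against log2 change with PAX5 (vertical axis), each over its own controls on the log2 of intensity plus 16, for 18193 genes, with colour giving the tests each gene passed. Ms4a1 lies at 7.15 and 0.26, H2-Aa at -0.17 and 6.15, and the 4 genes that passed both tests lie at the upper right.

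By list, the difference test passed for 5 receptor genes that were higher under EBF1 and 2 that were higher under PAX5, and adjusted over the list alone for 5 and 6 of 23. Higher gives the sign of the difference, so a gene that fell with EBF1 can be higher under PAX5 without a larger change there. The receptor list as a whole did not pass (median 0.05, camera adjusted p = 0.6, and adjusted p = 0.82 with an estimated correlation). Members higher under PAX5 were Siglecg (EBF1 minus PAX5 -3.57, limma adjusted p = 0.00014) and the kinase gene Syk (-1.18, 0.0076), named after their values were seen, as are the other list members here. Of 12 class II genes 7 were higher under PAX5 and 0 under EBF1, 9 and 0 adjusted over the list alone (camera adjusted p = 8.8e-16, and adjusted p = 0.17 with an estimated correlation). In this list H2-Ob read lower with EBF1, at 371, 300 and 372 against 1614, 847 and 631 in the set 1 controls. Of 22 early B-lineage factors 5 were higher under PAX5, Pax5, Irf4 (-1.85, 0.036), Irf8 (-2.59, 0.012), Klf2 (-1.82, 0.031) and Bcl6 (-1.36, 0.039), and 1 under EBF1, Pou2af1 (2.60, 0.038). The counts adjusted over the list alone were 8 and 2 (camera adjusted p = 0.00012, and adjusted p = 0.53 with an estimated correlation). These counts and list tests again include the transduced Pax5. Lmo2 (-1.56, 0.0098) and Hhex (-1.40, 0.012) were higher under PAX5 among 22 stem and progenitor genes, 4 adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.81 with an estimated correlation). Ccr2 (-3.87, 0.00079), Itgam (-2.14, 0.019) and Ccl3 (-2.86, 0.048) were higher under PAX5 among myeloid genes, 4 adjusted over the list alone. Rag1 (3.63, 0.033) was higher under EBF1 and Polm (-1.69, 0.019) under PAX5 among recombination genes, the same counts of 1 and 1 adjusted over the list alone.

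Smaller counts came from the other lists in the difference test. Dtx1 (-2.01, limma adjusted p = 0.00079) and Cd5 (-1.10, 0.025) were higher under PAX5 among T-lineage genes, where 2 were higher under EBF1 and 4 under PAX5 adjusted over the list alone. The other Dtx1 probe set had the reverse order, at 1.75 with EBF1 and -0.02 with PAX5, so the direction for Dtx1 depends on the probe set. Gzma under EBF1 and Klrd1 under PAX5 (-2.97, 0.043) passed among natural killer genes, 2 and 1 adjusted over the list alone, and Ly6d (4.72, 0.0048) and Itgax (-1.96, 0.004) among dendritic genes, 1 and 1 adjusted over the list alone. Phlda3 (1.02, 0.022) passed among p53 targets, 2 under EBF1 adjusted over the list alone, and Vwf (-1.46, 0.045) among erythroid genes, 1 and 1 adjusted over the list alone. The other 8 lists had 0 of 154 members past limma's test over all genes and 33 at unadjusted p under 0.05. Adjusted over the list alone, 4 interleukin-7 genes were higher under EBF1 and 3 under PAX5, 2 and 2 immediate-early genes, and 1 and 0 unfolded protein response genes. Limma's count was 0 within the list alone for mast cell (2 at unadjusted p under 0.05), stromal (2), cell cycle (2), chromatin architecture (3) and interferon genes (3). Camera placed the stromal (median 1, adjusted p = 0.0033), cell cycle (0.15, 0.017) and unfolded protein response lists (0.32, 0.00034) higher under EBF1, with adjusted p = 0.81, 0.81 and 0.53 with an estimated correlation, and the stromal signal lay in EBF1 array 3. Median, mean and camera direction differed in sign for the recombination, T-lineage, myeloid, dendritic and interleukin-7 lists.

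Cd24a, Hes1, Spib and Tnfrsf13c rose with both factors. Tnfrsf13c rose by 3.24 (SE 0.39) with EBF1 and 4.49 (SE 0.44) with PAX5, and Hes1 by 3.28 and 3.14, and the difference test did not pass for any of the 4 (limma adjusted p = 0.20 to 0.91). Independent lists of these sizes would share 0.28 genes, and a two-sided Fisher's exact test across genes, which are not independent replicates, gave p = 0.00017. No gene fell with both (0.0038 expected) and 0 genes passed in opposite directions (0.067 expected). Both comparisons rest on the same control hybridisations: in 100 simulations of unchanged groups against them, the mean number of shared calls was 0.01 and the highest 1. Such groups hold no changed genes, so here and in the paired simulations below a count near 0 was set in advance. It does not show what shared controls add to the overlap of genes that did change. Across genes the log2 changes correlated at 0.16 against 0.45 simulated, 55.2% of genes had the same sign against 64.7% simulated, and the covariance was 0.021 against 0.018, a difference of 0.003. These simulations leave out the pairing of control and EBF1 arrays. With a pair correlation of 0.28, the mean observed one, the simulated values were 0.38 for the correlation, 62.4% for the same sign, 0.013 for the covariance and 0 shared calls. The 3 controls cannot be split, so part of any excess may come from sharing them. Leaving out any 1 control array or EBF1 array 2 left 1 shared gene, leaving out PAX5 array 1 left 0, leaving out EBF1 array 3 left 24, of which 18 rose and 6 fell, and counting all 12 arrays separately left 23, of which 16 rose and 7 fell.

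The control arrays of the 2 sets were also compared, because both groups carry the same virus. Cpne7, which encodes a copine, read 6.16 ± 3.51 (SD, n = 3) in set 1 and 3669 ± 118 (n = 3) in set 2, and Gipc2 13.2 ± 4.72 and 449 ± 53.6, with log2 differences of 7.39 and 4.00 (limma adjusted p = 1.4e-10 and 6.4e-09). Rpl39, a ribosomal protein gene, read 7121 ± 200 in set 1 and 13.3 ± 3.23 in set 2, and Obsl1 1548 ± 89.5 and 16.8 ± 0.591, with differences of -7.93 and -5.57 (3.2e-10 and 1.8e-09). In all, 1661 genes differed, 1017 higher in set 2 and 644 higher in set 1, with 2197 at unadjusted p under 0.05. This fit counts the 6 arrays as separate samples, and with arrays of equal number paired over the sets 9131 genes differed, 8243 higher in set 2 and 888 higher in set 1. The median gene was shifted by 0.112 in log2 toward set 2, and with each array centred on its median 1695 genes differed, 865 higher and 830 lower. Without dim genes the count was 263. None of these 4 genes passed in the EBF1 or PAX5 comparisons, which stay within a set, where Rpl39 stood at -0.02 and -0.23. Some genes named for the factors also differed between the control sets: Pax5 (log2 difference -1.65, limma adjusted p = 0.00054), Igll1 (1.24, 0.0017), H2-Ab1 (1.13, 0.0011) and Siglecg (-1.33, 0.00049). Genes named after their values were seen also had unlike control levels, among them Cd74, with a log2 difference of -1.23. Cd79a read 8, 16 and 17 in set 1 and 67, 58 and 79 in set 2, and Klf2 185, 209 and 172 and 568, 602 and 385. The sizes of their changes therefore rest on the control level of their own set.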

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

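The tests of the 3 patterns weighed below and the splits of the control arrays were chosen only after the result was seen. A test of the difference itself singled out 353 genes whose response to EBF1 and PAX5 differed. EBF1 minus PAX5 log2 changes were 6.89 for Ms4a1, 6.62 for Tnnt2, 6.54 for Gzma, 6.28 for Vpreb1 and 6.08 for Apoa4, and -6.32 for H2-Aa, -6.28 for Hbb-bh1, -6.17 for H2-Eb1, -5.53 for H2-Ab1 and -5.38 for Pax5. Among the 10092 probe sets without a single gene symbol, which the comparisons did not use, 4 changed with EBF1 and 19 with PAX5 in limma's test over all 45037 probe sets. Of the 10 splits of the 3 control and 3 EBF1 arrays, 1, the real one, called as many genes (40, against 0 for the highest other). Of the 10 splits of the 6 control arrays, 1, the real one, separated 1661 genes, against 0 for the highest other. With 10 splits the share cannot fall under 0.05.

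The first pattern is that the control groups of the sets carry the same virus yet differ in 1661 genes. The highest robust SD between controls of equal number, 0.094, lay below the lowest between unequal numbers, 0.287, as the same hybridisation summarised in separate runs would give. If the pairs are the same hybridisations, their differences come from the processing and not from the cells. The transduced arrays followed their set: Rpl39 averaged 6999 in EBF1 and 9.43 in PAX5 cells, and Cpne7 5.4 and 3601. Whether the arrays summarised together set the control level of the genes called with each factor stays open. The median control difference, set 2 minus set 1, was 0.307 for genes raised by EBF1 and 0.08 for genes raised by PAX5 (5th to 95th percentile of medians of random lists 0.135 to 0.158 and 0.121 to 0.135). Calling genes against the controls of their own set favours these directions by selection. No biological explanation was tested, because the design gives none.

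The second pattern is the stromal signal and weaker response of EBF1 array 3, for which a response to EBF1 as the whole cause is argued against, since the stromal list's median was 0.443, -0.095 and 2.142 in EBF1 arrays 1, 2 and 3 while the receptor list rose by 0.45 in array 2. Stromal cells or their RNA in that sample are a candidate explanation: across the list's 19 genes the excess of array 3 over the other EBF1 arrays correlated with that of control array 1 over the other controls (Spearman's rho 0.832), with Cxcl12 at 3366 and Bgn at 2727 in array 3, although the sort for GFP would be expected to remove feeder cells. Cxcl12 did not follow Bgn across the other arrays. It read 128 and 129 in control arrays 1 and 3 of set 1, where Bgn read 550 and 73. In PAX5 arrays 2 and 3 Cxcl12 read 560 and 551, and Bgn 287 and 246. No other list holds any of the 19, and 2 of them read above the median of all probe sets in control array 2, the control with the lowest stromal signal. Fewer responding cells stays open: array 3 showed a median share of 0.23 of the change in arrays 1 and 2 for 190 genes that rose and 0.47 for 118 that fell, a gap of -0.238 (bootstrap interval over genes -0.31 to -0.14) between the limits set for either outcome. That interval resamples genes, not arrays, so it holds no spread between arrays. Picking the genes by arrays 1 and 2 alone lowers both shares by selection, by an amount that was not measured. Dilution and weaker EBF1 activity cannot be told apart for these genes, since whether any probe reads the EBF1 insert is not known.

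The third pattern is the embryonic globin signal with PAX5: Hbb-bh1 rose on all 3 of its probe sets by 5.89 to 6.20 and Hbb-y, named after its values were seen, by 1.49 to 3.35 on its 3, while Hba-a1 stood at -0.82 (adjusted p = 0.22 by limma) and Hba-x at -0.12, both dim. The probe set shared by the adult beta-globin genes stood at 1.97 (adjusted p = 0.27 over all probe sets), with 2500 to 2618 in the PAX5 arrays and 419 to 1052 in their controls, and a dim Hbb-b2 probe set rose by 0.94 (0.031). A single odd array is argued against, since the largest and smallest rise of Hbb-bh1 among the PAX5 arrays differed 1.27-fold. Erythroid cells stay open: the median change of the 12 erythroid and megakaryocyte genes was 0.021 (bootstrap interval over genes, not arrays, -0.14 to 0.38), but its members go both ways and 7 read below the median of all probe sets in the set 2 controls, and 6 alpha-type globin probe sets read at most 119 on any array, so that they can respond is not shown. Activation of the locus by PAX5 and a feature of the PAX5 culture or virus stock also stay open, untested, and the call of Hbb-bh1 was lost without PAX5 array 1 (limma adjusted p = 0.097) and with a pseudocount of 1 (0.06), in a range of 0.00027 to 0.097 over the alternatives.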

How the results depend on the processing

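Chosen only after the data were seen were reporting the count of all 12 arrays separately (the first design) as an alternative, PAX5 arrays 2 and 3 as 2 samples, the replicate block with each hybridisation once, and pairing control arrays over the sets; the others were planned. Of 54 named gene results past the threshold 26 kept it under every alternative run, 28 lost it under at least 1 and 0 reversed, with most losses without PAX5 array 1 (26 of 54), where the lone PAX5 sample is assumed to vary like the other groups. Genes passing with EBF1 (40) numbered 10 with arrays of 1 set only, 93 with trend and robust variance, 66 with array weights, 11 at adjusted p under 0.01, 23 and 10 with pseudocounts 1 and 64, 201 with 12 arrays counted and 88 with PAX5 arrays unmerged. Those with PAX5 (159) numbered 105 with 1 set only, 67 at 0.01, 84 with pseudocount 1, 357 with 12 arrays and 301 unmerged. Differing responses (353) numbered 535 with trend, 777 with weights, 105 at 0.01, 194 with pseudocount 1, 156 with 12 arrays and 879 unmerged. Shared genes (4) numbered 2 with 1 set only, 11 with trend, 1 at 0.01, 1 with either pseudocount, 23 with 12 arrays and 9 unmerged. The control sets (1661) differed in 263 genes without dim genes in 4120 probe sets when these were the units, and in 9131 genes with arrays of equal number paired over the sets. Lists passing for EBF1 (4), PAX5 (6) and the difference (6) were 0 each with an estimated correlation and 1, 3 and 3 by fry, and 7 for EBF1 without dim genes. With the replicate block, which pairs the EBF1 arrays, 69 genes passed with EBF1 with each hybridisation once and 161 with 12 arrays counted, where 425 passed with PAX5, 207 differed and 25 were shared. In set 2, whose arrays share only a number, deviations of equal numbers correlated at 0.24, 0.08 and 0.18, and every PAX5 array correlated best with the control of its own number, a hint from the data only; with the block and 12 arrays 4, 6 and 5 lists passed. Leaving out 1 array at a time gave 10 to 406 genes for EBF1, 28 to 176 for PAX5, 55 to 575 for the difference, 1385 to 1693 for the control sets, 0 to 24 shared genes, and 3 to 6, 5 to 6 and 4 to 6 lists. Fewer arrays in a fit leave fewer residual degrees of freedom, and counting an array 2 times adds some; for the other settings the cause was not tested. Low signal limits dim genes, where the pseudocount sets the fold.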

Other observations

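The genes and list counts in the next paragraph were chosen after the data were seen, although leaving out each array in turn was planned.

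Without EBF1 array 3, which carried the stromal signal, 406 genes passed with EBF1, 234 higher and 172 lower, against 40 with it, and all 40 were among them. Some members of lists for other lineages then passed with lower values: Gata3 and Tox, factors of T cell development, at -1.69 and -1.25 in log2 (limma adjusted p = 0.00094 and 0.017), Id2 and Zbtb16, regulators of innate lymphoid cells, at -1.32 and -1.5 (0.0078 and 0.022), and the natural killer genes Il18r1 and Klrd1 at -1.96 and -2.29 (0.0025 and 0.028). The 3 myeloid genes that passed were the Fc receptor gene Fcgr3 at -1.59 (0.0064), the chemokine gene Ccl3 at -2.73 (0.0066) and the integrin gene Itgam at -1.63 (0.049). Also lower were the dendritic list genes Ccr9 at -1.71 (0.0089) and Cox6a2 at -2.06 (0.041), and the progenitor genes Cd34 at -2.08 (0.0022) and Mycn at -1.45 (0.018). More B-lineage genes passed as well: Blnk rose by 4.03 (0.0023), Rag1 by 3.13 (0.044), Pou2af1 by 2.90 (0.0088), Bst1 by 2.04 (0.0025), Cd72 by 1.36 (0.017) and Bcl11a by 1.27 (0.032). By list, 9 of 23 receptor genes and 4 of 22 early B-lineage factors rose, and 4 of 21 natural killer, 3 of 21 T-lineage, 3 of 26 myeloid, 3 of 15 dendritic and 2 of 22 progenitor genes fell, while Hes1 (3.74, 6e-04), Gzma (6.86, 3.2e-06) and Ly6d (4.85, 2.1e-05) of the T-lineage, natural killer and dendritic lists rose. In this fit 6 lists passed camera, among them the T-lineage (median -0.12, adjusted p = 0.011), natural killer (-0.23, 0.034) and progenitor lists (-0.5, 2.7e-06), while the myeloid (0.04, 0.13) and dendritic lists (-0.1, 0.13) did not, and 0 lists passed with an estimated correlation (lowest adjusted p = 0.19). In interleukin-7 signalling Cish rose by 2.14 (0.012) and Bcl2l1, a survival gene, by 0.87 (0.033), while Pim2 stood at -0.96 (0.013). These calls rest on 2 EBF1 arrays, and with array 3 included none of Gata3, Tox, Id2, Zbtb16, Il18r1, Klrd1, Fcgr3, Ccl3, Itgam, Ccr9, Cox6a2, Cd34 or Mycn passed. In array 3 Gata3 read 75, above the set 1 controls (58, 56 and 56), and so did Pim2 at 766 (624, 761 and 625). Ccr9 at 5163 and Cd34 at 2300 lay within the range of those controls. The other genes named as lower read below all of these controls in array 3.

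The chromosome organisers of the chromatin list, which bear on the study's subject, gave no call with either factor in limma's test (1 of 28 at unadjusted p under 0.05 in each comparison). Ctcf stood at 0.06 (SE 0.13) with EBF1 and 0.11 (SE 0.14) with PAX5, Rad21 of cohesin at -0.07 and 0.03, and Satb1 at -0.23 and 0.13.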
